A study of Mus musculus with 66 samples.

How the data were processed

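RNA was measured in 66 libraries of mouse splenic B cells, 33 from germinal centre (GC) B cells and 33 from naive B cells. Per the labels' protocols, cells came from BALB/c mice carrying a B1-8 IgM antigen receptor transgene, were purified with beads and stimulated, and libraries were made with a SMART-Seq v4 low-input kit. Per the submitters' processing notes, the tools used upstream were FastQC 0.11.7, Trim Galore 0.6.5, STAR 2.6.1a, featureCounts from Subread 2.0.1 and limma, and the genome build was mm10. The notes give neither their order nor their settings.

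The authors deposited 1 column of log2 values per library, for the same 23420 gene symbols in each. Back-transformed, the deposited log2 values of a library summed to between 926830 and 1065945, close to what CPM values would give. Read counts could not be recovered from them, so sequencing depth is unknown and no value carries a counting interval. The commonest low value was -5.094 in 34 libraries and -4.833 in the other 32. Those groups of libraries matched a division already visible in the sample titles and file headers. Set A holds anti-CD40 replicates 1 to 3, IL-21 and IL-21 plus anti-CD40. Set B holds anti-CD40 replicates 4 and 5, no stimulation, anti-IgM and anti-IgM plus anti-CD40. The sets were thus normalized separately, and the fit described below links them only through the anti-CD40 libraries that both contain. Where deposited levels of marker transcripts are given for both sets, they are not adjusted for this. Within a set the medians of the genes tested were nearly equal, from 4.628 to 4.646 in set A and from 4.793 to 4.84 in set B. Many libraries also shared the same highest value. Libraries scaled to near-equal distributions tend to show similar numbers of rises and falls, so that balance may come from the scaling.

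Genes with a log2 value above 1 in at least 4 libraries were tested, which left 11264. The tests planned before the data were examined were for read counts. Because the files hold log2 values, the same design was fitted with limma 3.58.1 in R 4.3.3, with moderation that allows a mean-variance trend and is robust to outlying genes (statmod 1.5.0). The fit had 24 groups of cell type, stimulus and time and a library set term within each cell type, leaving 40 residual degrees of freedom. An effect is the mean of the 2 h and 4 h effects. P-values are two-sided and adjusted by Benjamini-Hochberg over all genes tested within a comparison, and a gene was called at an adjusted p under 0.05. There were 24 comparisons with a direction and 2 tests of time dependence.

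Named genes followed a rule written before the data were examined. It took the 6 largest rises and 6 largest falls among called genes with a mean log2 value of at least 4 over the groups compared and the same sign at both times, leaving out predicted genes, receptor segments and small RNAs. It added 28 focus genes, of which 27 were tested, and up to 4 members of each gene list described, those with the smallest adjusted p. Some genes that this rule names are not reported here, though they stay in all tests and counts. The 25 gene lists were fixed beforehand and tested with camera at a preset correlation of 0.01, adjusted over all 600 tests of a list in a comparison. Of these tests 211 passed, and 107 passed when the correlation between genes was estimated. Symbols follow the files, and older symbols were matched through RefSeq synonyms. Coordinates are from GENCODE for GRCm38, the assembly called mm10, and were found for 363 of the 375 genes the rule could name.

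Replicates carry numbers in the labels. In set B, deviations from the group mean correlated across genes between libraries of the same cell type and number in all 32 pairs of GC libraries, from 0.54 to 0.73, and in all 32 naive pairs, from 0.59 to 0.73. In set A only 4 of 40 GC pairs and 5 of 40 naive pairs exceeded 0.1. The numbers therefore pair the libraries of set B, and values from a fit with the replicate number as a block stand beside results they move by more than 1.5 times. Within groups, correlations between replicates ran from 0.942 to 0.988. Nothing in the labels says whether replicates came from separate mice, so p-values measure the spread between these samples, which may be technical.

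The fit was tested on simulated data in which some of the 11264 genes were changed in the comparison of anti-CD40 with no stimulation in GC B cells. It recovered 68 of 100 genes changed by 1 on the log2 scale and 81 of 100 changed by 2, with 6 false calls. For IL-21 against no stimulation in GC B cells it recovered 58 and 83 of 100, again with 6 false calls. The simulated noise was independent between libraries and the set term exactly additive, whereas real libraries of set B deviate together by replicate number. The simulation therefore checks the fit under its own assumptions and does not give error rates for these data. Alternatives were the fit without the set term, no filter, a stricter filter (a log2 value above 3 in at least 20 libraries), separate fits per cell type, the replicate block, other set terms, other scaling and moderation, fits within a set, and leaving out each library in turn. Tests on read counts were not run.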

Results

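The series followed how B cells of the germinal centre, the site where B cells mutate their antigen receptors and compete for T cell help, respond to the signals they meet there, in parallel with naive B cells. Cells from mouse spleen were cultured for 2 h or 4 h without stimulus or with anti-CD40 (an antibody that mimics T cell help), anti-IgM (which crosslinks the B cell receptor), IL-21 (a cytokine of follicular helper T cells), anti-IgM plus anti-CD40, or IL-21 plus anti-CD40. The 66 libraries fell into 24 groups of 2 to 5. Expression is given as deposited log2 values, sequencing depth is unknown, and changes are log2 fold changes ± standard error from the limma fit unless stated.

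Unstimulated GC and naive B cells differed in the genes that define them. S1pr2, a receptor that retains cells in follicles, was higher in GC B cells by 5.70 ± 0.13. Klf3 was lower at -6.10 ± 0.14 and Ly6d at -5.97 ± 0.18. Of 14 listed GC identity genes 13 were higher, and all 13 measured naive identity genes were lower. All 13 genes of the G2/M list were higher, among them Kif11 (5.14 ± 0.17) and Nek2 outside the list (5.66 ± 0.18).

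Genes of acute activation lay lower in unstimulated GC B cells. Of 18 immediate early genes 15 were lower, including Jun (-3.16), Ier2 (-3.42) and Junb (-2.67), and Myc, the growth regulator, was at -2.29 ± 0.17. Of 21 interferon-stimulated genes 16 were lower, with Rtp4 at -6.28, although that list's call was lost with an estimated correlation (adjusted p = 0.11). Of 23 genes of ribosome biogenesis 17 were lower, with Srm at -2.80, and the adjusted p was 0.18 with an estimated correlation. In total 7331 genes differed, 3365 higher and 3966 lower in GC B cells, and 21 of 27 focus genes were called (22 adjusted over the list alone). Markers of other cells were also lower in the GC libraries: 7 of 10 myeloid genes, including Lyz2 (-3.68), 5 of 7 T cell genes, including Cd3e (-3.85), and 3 of 3 erythroid genes. Stromal Col1a2 went the other way at 3.02.

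Anti-CD40 raised targets of NF-kB, the transcription factor downstream of CD40, in both cell types. Of 19 listed targets 16 rose in GC B cells and none fell (adjusted p = 9e-34, and 2.5e-07 with an estimated correlation). Ebi3, a cytokine subunit, rose by 4.98 ± 0.20, the survival gene Bcl2l1 (chromosome 2, 152780668 to 152831728) by 4.13 ± 0.19, Traf1 by 2.79 and Nfkbia by 3.36 ± 0.22. Of 12 BCL2 family genes 7 rose, with Bcl2a1d at 3.44. Myc (chromosome 15, 61985391 to 61990374) rose by 2.77 ± 0.17, from 5.43 ± 0.44 (SD, n = 2) without stimulus to 8.53 ± 0.14 (SD, n = 2) at 2 h among libraries of set B, and 16 of 23 ribosome biogenesis genes rose, led by Gnl3 (1.76). Other genes that rose most were Tnfsf9 (4.58 ± 0.26), Mgll (4.20 ± 0.19), Fscn1 (3.94 ± 0.59) and Siah2 (3.45 ± 0.53).

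GC identity genes fell in GC B cells given anti-CD40: 8 of 14 were lower, including S1pr2 (-2.77 ± 0.13) and Efnb1 (-2.48 ± 0.17), while Fas of the same list rose by 2.06. S1pr1 (-3.48 ± 0.16), Rgs1 (-2.41 ± 0.23) and Rgs2 (-2.31 ± 0.22) also fell. Bcl6, the repressor that maintains the GC state, was at -0.79 ± 0.21. Of 13 G2/M genes 8 fell, with Kif20a at -0.91, though that call was lost with an estimated correlation (adjusted p = 0.12). In total 1276 genes rose and 1177 fell, and 19 of 27 focus genes were called (21 adjusted over the list alone). With the replicate block 3888 genes were called in place of 2453. Within set B alone the count was 1571, and without the set term 4360.

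In naive B cells anti-CD40 raised Il2ra, a chain of the IL-2 receptor, by 5.01 ± 0.42, Bcl2l1 by 4.89 ± 0.19, Fas by 3.84 ± 0.22, Ccnd2, a cyclin of early G1, by 3.71 ± 0.24 and Icam1 by 3.46 ± 0.18. S1pr1 (-4.60 ± 0.16), March1 (-3.68 ± 0.27), Fcrla (-3.64 ± 0.15) and Susd3 (-3.32 ± 0.27) fell most. Of 19 NF-kB targets 16 rose, and 10 of 11 genes of the FOXO and KLF2 quiescence list fell, including Pik3ip1 (-2.41), Btg2 (-1.76) and Ccng2 (-2.60). There were 2207 genes higher and 2190 lower, and 22 of 27 focus genes were called (22 adjusted over the list alone).

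The effect of anti-CD40 differed between cell types for 1018 genes (2319 with the replicate block, 463 within set B, and 1652 without the set term). Bcl6 (chromosome 16, 23965052 to 23988852) rose by 1.55 ± 0.21 in naive cells, and the GC effect differed from the naive one by -2.34 ± 0.30. Myc responded more in GC B cells, by 1.20 ± 0.24, as did Batf, a partner of AP-1 and IRF4, by 2.02 ± 0.33, and Nfkbia by 1.23 ± 0.31. Since Myc lay lower in unstimulated GC B cells, its larger rise does not mean a higher level. Of 11 quiescence genes 5 had a higher effect in GC B cells and 0 a lower one (adjusted p = 0.0012 with an estimated correlation), with differences of 2.70 for Pik3ip1, which was at 0.29 in GC B cells and not called, and 1.82 for Sesn1. GC identity genes went the other way, with 6 of 14 called lower, among them S1pr2 (-2.45 ± 0.19).

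**Figure D1:**
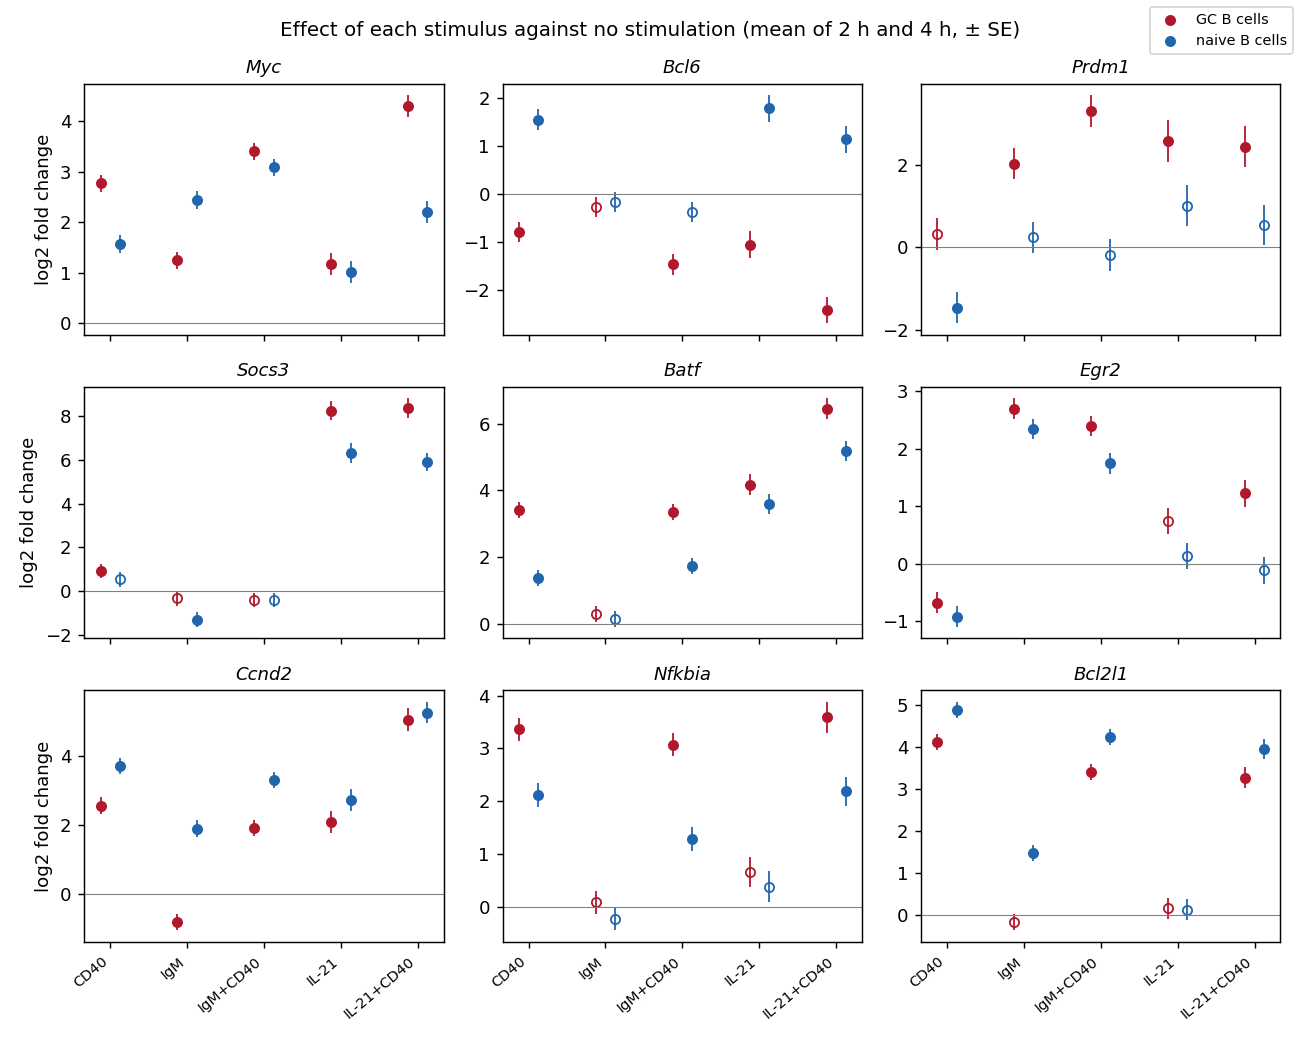
Log2 fold change (vertical axis, ± SE) of 9 focus genes for each stimulus against no stimulation (horizontal axis), in GC B cells (red) and naive B cells (blue). Filled points passed an adjusted p of 0.05 and open points did not. Bcl6 went in opposite directions in the cell types with anti-CD40 (-0.79 and 1.55), and Socs3 rose with IL-21 in both (8.25 and 6.32).

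Anti-IgM induced the immediate early response of the B cell receptor. Among GC B cells Egr2 (chromosome 10, 67535475 to 67542188) rose by 2.69 ± 0.18, Egr1 by 2.49 ± 0.27 and Nr4a1 by 1.31 ± 0.30, and 11 of 18 immediate early genes rose with none falling (adjusted p = 2.5e-10, and 0.0011 with an estimated correlation). Spp1 (3.04 ± 0.31), Gem (3.02 ± 0.15), S1pr3 (2.72 ± 0.17) and Rnf122 (2.72 ± 0.24) rose most along with Fam167a (2.78 ± 0.60). Prdm1 (chromosome 10, 44437177 to 44528501), the regulator of plasma cell differentiation, rose by 2.02 ± 0.38, and Myc by 1.25 ± 0.17. Prdm1 was low in unstimulated GC B cells, at -0.55 ± 1.26 (SD, n = 2) at 2 h and 0.75 ± 0.6 at 4 h. Both means lie under the filter's log2 value of 1. Since depth is unknown, the size of Prdm1 effects in GC B cells, here and below, is uncertain. Dark zone genes fell, 5 of 8, including Ccnd3 (-1.56), Polh (-1.33) and Tcf3 (-1.22), and B3gnt8 (-3.21 ± 0.32), Tifa (-2.92 ± 0.18) and Otub2 (-2.74 ± 0.25) fell most. Of 19 NF-kB targets 7 rose, including Nfkbie (1.56), Cd83 (1.59) and Traf1 (1.15), and 2 fell, while Nfkbia (0.10 ± 0.22) and Tnfaip3 (-0.01 ± 0.23) did not pass. That list's call was lost with an estimated correlation (adjusted p = 0.13). In total 905 genes rose and 635 fell, and 13 of 27 focus genes were called (14 adjusted over the list alone). With the replicate block 2685 genes were called in place of 1540, and within set B alone 1019. The T cell genes Lck (1.42) and Lat (1.69) rose while Cd3e was at 0.74 and not called.

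Naive B cells changed metabolic genes with anti-IgM. Of 17 genes of amino acid transport and the ATF4 response 15 rose, including Psat1 (2.18), Slc1a5 (1.79) and Mthfd2 (1.58), with an adjusted p of 0.0031 with an estimated correlation. Of 16 glycolysis genes 12 rose, with Slc16a1 at 1.99, but that call was lost with an estimated correlation (adjusted p = 0.055). Spp1 (4.47 ± 0.31), Plau (4.19 ± 0.39), Bcat1 (3.30 ± 0.19), Nr4a2 (3.13 ± 0.29) and Fam83g (3.08 ± 0.16) rose most, and Icosl (-3.75 ± 0.20), Cd55 (-3.35 ± 0.18), Il10ra (-3.21 ± 0.26), Cnp (-3.20 ± 0.20) and Cpm (-3.18 ± 0.14) fell most. There were 2256 genes higher and 2264 lower, and 17 of 27 focus genes were called (17 adjusted over the list alone).

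Differences between cell types in the anti-IgM effect numbered 1877 genes (3368 with the replicate block, 997 within set B). Myc rose less in GC B cells, at -1.19 ± 0.24. Ccnd2 fell in GC B cells (-0.80) and rose in naive B cells (1.90), a difference of -2.71 ± 0.34, and the GC effect was also lower for Bcl2l1 (-1.64 ± 0.27), Bcat1 (-2.78 ± 0.27) and Psat1 (-1.92 ± 0.19). Prdm1 responded more, by 1.78 ± 0.54, and Egr1 by 1.17 ± 0.38. For Prdm1 the larger effect does not mean a higher level. With anti-IgM it averaged 2.05 at 2 h and 2.18 at 4 h in GC B cells, against 4.37 and 3.62 in naive B cells. For Sesn1 the difference was 3.19 ± 0.21 and for S1pr1 2.68 ± 0.22, against naive effects of -2.29 for Sesn1 and -2.39 for S1pr1. In the amino acid list 11 of 17 genes had a lower effect in GC B cells (adjusted p = 0.0088 with an estimated correlation).

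With anti-IgM plus anti-CD40, 16 of 19 NF-kB targets and 11 of 18 immediate early genes rose in GC B cells and 0 fell (adjusted p = 1.6e-05 and 0.012 with an estimated correlation). Myc rose in GC B cells by 3.40 ± 0.17, Irf4 by 3.69 ± 0.43, Prdm1 by 3.30 ± 0.38 and Id2 by 3.58 ± 0.13, and Gng4 (6.06 ± 0.36), Mreg (4.70 ± 0.28) and Tnfsf9 (4.07 ± 0.26) rose most. Gcsam (-3.28 ± 0.31), Otub2 (-4.02 ± 0.25) and Xkrx (-3.43 ± 0.39) fell. Of 23 ribosome biogenesis genes 21 rose, with Gnl3 at 2.46 and Nolc1 at 2.41 (adjusted p = 0.01 with an estimated correlation). All 13 G2/M genes fell, with Cenpe at -1.60 (adjusted p = 0.069 with an estimated correlation), and 7 of 8 dark zone genes fell, with Ccnd3 at -2.57. Totals were 1993 higher and 1961 lower, with 22 of 27 focus genes called (22 adjusted over the list alone). In these libraries Lyz2 (-1.16), Beta-s (-1.31) and Pecam1 (-1.54), markers of other cells, also fell.

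The combination raised in naive B cells Il2ra (5.26 ± 0.42), Gng4 (4.95 ± 0.36), Fam83g (4.28 ± 0.16) and Adm (4.00 ± 0.31) and lowered S1pr1 (-5.43 ± 0.16), Fcrla (-4.90 ± 0.15), March1 (-4.47 ± 0.27) and Sgms1 (-4.17 ± 0.11). All 23 ribosome biogenesis genes rose, with Rrp9 at 1.68 and Polr1b at 1.63 (adjusted p = 0.068 with an estimated correlation), and 10 of 11 quiescence genes fell. There were 2880 genes higher and 2932 lower, and 16 of 27 focus genes were called (16 adjusted over the list alone). The combination's effect differed between cell types for 2242 genes (3700 with the replicate block, and 1342 within set B). Prdm1 responded more in GC B cells by 3.49 ± 0.54 and Cd40 by 1.55 ± 0.23, whereas S1pr2 (-2.77 ± 0.19), Cited2 (-3.69 ± 0.46) and Polh (-2.70 ± 0.33) lay lower. The level Prdm1 reached with both stimuli was 3.02 at 2 h and 3.78 at 4 h in GC B cells, and 3.66 and 3.46 in naive B cells.

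Set against anti-CD40 alone, added anti-IgM raised 10 of 18 immediate early genes in GC B cells and lowered 2 (adjusted p = 0.0031 with an estimated correlation). Egr2 was higher by 3.07 ± 0.18, Egr1 by 2.39 ± 0.27, Rgs1 by 3.08 ± 0.23, Irs2 by 3.24 ± 0.22, Gng4 by 3.91 ± 0.36 and Prdm1 by 2.98 ± 0.38. Fscn1 (-3.05 ± 0.59), Glul (-2.39 ± 0.34), Icosl (-2.14 ± 0.20) and Pim2 (-2.05 ± 0.20) were lower. In naive B cells Plau (3.97 ± 0.39), Cd63 (3.48 ± 0.23), Ahr (3.09 ± 0.21) and Nr4a2 (3.05 ± 0.29) were higher, and the receptor subunit Cd79b (-2.85 ± 0.12), Ly6d (-2.86 ± 0.18), Il16 (-2.84 ± 0.13) and Tmem173 (-2.70 ± 0.11) were lower. Of 19 NF-kB targets 9 were lower and 2 higher in naive cells, with Ebi3 at -2.26 and Birc3 at -1.53 (adjusted p = 0.069 with an estimated correlation). In GC B cells 1702 genes differed (3069 with the replicate block, 1049 within set B, 3269 without the set term), and in naive B cells 2362 (3835 with the block, 3930 without the set term). Focus genes called were 10 and 15 of 27 (12 and 16 adjusted over the list alone).

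The combination departed from the sum of the separate log2 effects mainly in naive cells. There Bcl2l1 lay below the sum at -2.12 ± 0.27, Ccnd2 at -2.31 ± 0.34, Il2ra at -2.49 ± 0.60, Marcksl1 at -2.51 ± 0.16 and Myc at -0.93 ± 0.24, and 8 of 19 NF-kB targets lay below with none above (adjusted p = 0.0018 with an estimated correlation). Slfn2 (2.15 ± 0.18), Cd2 (1.98 ± 0.27) and Traf5 (1.96 ± 0.24) lay above it. In naive cells 958 genes departed, 445 above and 513 below (2448 with the replicate block, 388 within set B). GC B cells had 60 such genes (303 with the block, 18 within set B), including Cd83 (-1.37 ± 0.24), Pim2 (-1.83 ± 0.28), Cd69 (-1.37 ± 0.19) and Gadd45b (1.53 ± 0.19), and Myc was at -0.62 ± 0.24 without passing. Whether the cell types differed in these departures was not tested. The GC count fell to 33 without the 2 h anti-CD40 replicate 5, 36 without the 2 h unstimulated replicate 2, 37 without the 4 h unstimulated replicate 2 and 39 without the 4 h anti-IgM replicate 1. Focus genes called were 1 in GC and 9 in naive cells (2 and 10 adjusted over the list alone).

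IL-21 acted on JAK-STAT targets. Socs3 (chromosome 11, 117966079 to 117970047), a feedback inhibitor of cytokine receptors, rose by 8.25 ± 0.44 in GC and 6.32 ± 0.44 in naive B cells, Batf (chromosome 12, 85686669 to 85709087) by 4.17 ± 0.31 and 3.59 ± 0.31, and Plscr1 by 4.38 ± 0.31 and 5.02 ± 0.31. Of 14 listed JAK-STAT genes 12 rose in GC and 13 in naive B cells (adjusted p = 1.7e-09 and 2.5e-07 with an estimated correlation). Csf1 (4.77 ± 0.38), Il1r1 (4.47 ± 0.38) and Serpinb1a (3.87 ± 0.20) also rose most in GC B cells, and Nfil3 (4.22 ± 0.25), Socs1 (3.80 ± 0.36) and Il2ra (3.60 ± 0.56) in naive B cells. Prdm1 rose by 2.57 ± 0.50 in GC B cells and Myc by 1.18 ± 0.22 and 1.02 ± 0.22 in GC and naive cells.

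Among genes that fell with IL-21 were Ets2 (-1.88 at 2 h and -2.12 at 4 h), Icosl (-1.34 ± 0.27) and Arl5c (-1.27 ± 0.12) in GC B cells, and Klf2 (-1.95 ± 0.54), Rassf3 (-1.94 ± 0.44), Rgs2 (-1.78 ± 0.29) and Cat (-1.77 ± 0.28) in naive B cells. Bcl6 fell in GC B cells, at -1.06 ± 0.28, and rose in naive B cells by 1.78 ± 0.28. This difference of -2.84 ± 0.40 was among 69 genes whose IL-21 effect differed between cell types (312 with the replicate block, 1358 without the set term), with Il21r (-1.46 ± 0.26), Mxd1 (-2.26 ± 0.27), Serpinb1a (2.39 ± 0.28) and Tiparp (2.06 ± 0.24). That count was 40 without the 2 h naive IL-21 replicate 1, 44 without the 2 h naive unstimulated replicate 1 and 42 without the 4 h naive unstimulated replicate 2. IL-21 changed 391 genes in GC B cells, 270 higher and 121 lower, and 1169 in naive B cells, 622 higher and 547 lower. With the replicate block the counts were 920 and 2397. Focus genes called were 8 and 11 of 27 (11 and 13 adjusted over the list alone). IL-21 libraries are all of set A and unstimulated ones of set B, and without the set term the counts were 4929 and 4718.

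IL-21 plus anti-CD40 raised Myc in GC B cells by 4.29 ± 0.22, to 10.18 ± 0.19 (SD, n = 3) at 2 h, together with Socs3 (8.38 ± 0.44), Batf (6.44 ± 0.31), Gbp1 (5.56 ± 0.32), Gadd45g (5.36 ± 0.31) and Ccnd2 (5.05 ± 0.32). Rgs2 (-3.83 ± 0.28), Cpm (-3.25 ± 0.18), Ccng2 (-3.04 ± 0.27), Eif2ak3 (-2.87 ± 0.30) and Bcl6 (-2.42 ± 0.28) fell. Of 23 ribosome biogenesis genes 19 rose, with Nop2 at 1.73 (adjusted p = 0.012 with an estimated correlation). Among naive B cells Il2ra (6.01 ± 0.54), Socs3 (5.91 ± 0.43), Slamf1 (5.46 ± 0.16) and Ccnd2 (5.25 ± 0.31) rose and Rnase6 (-4.16 ± 0.34), S1pr1 (-3.82 ± 0.20) and Rapgef4 (-3.73 ± 0.22) fell. The combination called 1423 genes higher and 1530 lower in GC B cells, and 2102 higher and 2197 lower in naive B cells. With the replicate block the GC count of 2953 became 4507, and without the set term the counts were 6780 and 6687. Focus genes called were 19 and 19 of 27 (20 and 20 adjusted over the list alone).

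This combination's effect differed between cell types for 658 genes (1643 with the replicate block, 3385 without the set term). Myc responded more in GC B cells by 2.09 ± 0.31, and Socs3 by 2.47 ± 0.61. These are differences in effect and not in the level reached. Myc lay lower in unstimulated GC than naive B cells, and Socs3 averaged -0.12 over GC libraries of set B, under the filter's log2 value of 1. Pik3ip1 rose in GC B cells (1.02) and fell in naive B cells (-2.56), a difference of 3.58 ± 0.28. The GC effect lay below the naive one for Bcl6 (-3.56 ± 0.40), Mxd1 (-2.74 ± 0.27), Lmnb1 (-2.47 ± 0.33) and Foxm1 (-2.29 ± 0.52). Of 18 G1/S genes 6 were lower in the GC effect and 1 higher, with Mcm5 at -1.11 and Cdc6 at -1.56 (adjusted p = 0.011 with an estimated correlation).

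Added to anti-CD40, IL-21 raised Socs3 by 7.47 ± 0.29, Gadd45g by 4.90 ± 0.20, Csf1 by 4.47 ± 0.25, Serpina3g by 3.81 ± 0.13, Myc by 1.51 ± 0.15 and Prdm1 by 2.11 ± 0.33 in GC B cells, and lowered Cpm (-2.03 ± 0.12), Arl5c (-1.97 ± 0.08), Cnr2 (-1.92 ± 0.15) and Bcl6 (-1.62 ± 0.18). In naive B cells it raised Batf by 3.80 ± 0.19, Nfil3 by 3.15 ± 0.15, Slamf1 by 2.95 ± 0.10 and Myc by 0.63 ± 0.14, and lowered Hvcn1 (-1.87 ± 0.13), Il10ra (-1.76 ± 0.21) and Cd79b (-1.34 ± 0.10). In GC B cells 2006 genes differed, 1001 higher and 1005 lower, and in naive B cells 1208, 484 higher and 724 lower. The counts were 3512 and 2304 with the replicate block, 3260 and 1773 without the set term, and 3739 and 2738 within set A, where both groups have libraries. Focus genes called were 13 and 12 of 27 (14 and 15 adjusted over the list alone).

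Departures from the sum of separate log2 effects of IL-21 and anti-CD40 were called for 171 genes in GC and 332 in naive B cells (705 and 1066 with the replicate block, 330 and 532 without the set term). In GC B cells Tagap (2.08 ± 0.21) and Kcna3 (1.49 ± 0.31) lay above the sum and Gem (-1.38 ± 0.19), Tiparp (-1.30 ± 0.16) and Batf (-1.13 ± 0.31) below, and Myc was at 0.33 ± 0.22 without passing. In naive B cells Bcl6 (-2.19 ± 0.28), Plscr1 (-2.28 ± 0.31), Il2ra (-2.61 ± 0.56) and Pim1 (-1.48 ± 0.16) lay below and Siglecg (1.77 ± 0.27) and Bcl11a (1.31 ± 0.21) above. The naive count was 216 without the 2 h unstimulated replicate 1 and 218 without the 2 h IL-21 replicate 2. Focus genes called were 4 and 8 of 27 (4 and 11 adjusted over the list alone).

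**Figure D2:**
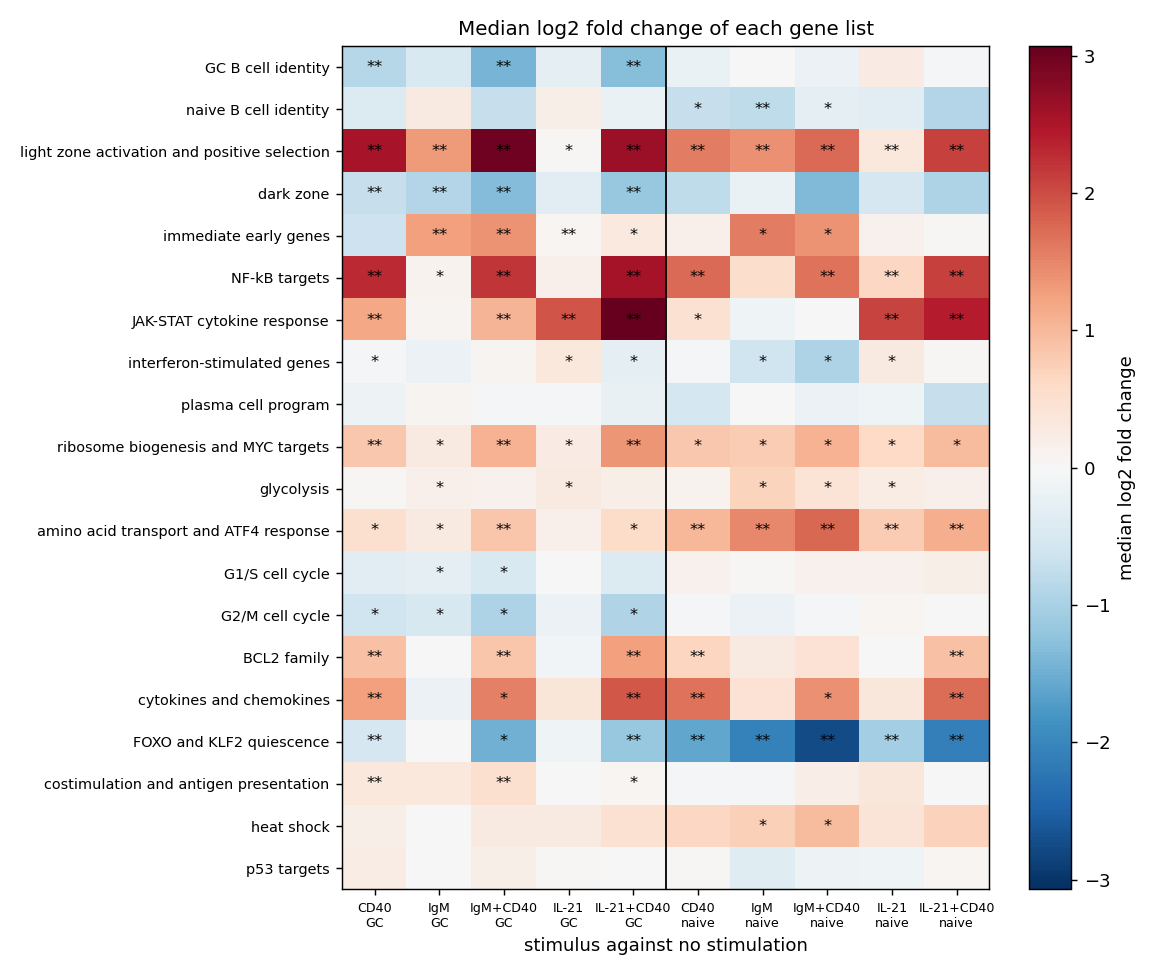
Median log2 fold change (colour) of the tested members of 20 gene lists (rows) for each stimulus against no stimulation (columns) in GC and naive B cells. A single star marks lists with an adjusted p under 0.05 at the preset correlation, and a double star those that also passed with an estimated correlation. The NF-kB list had medians of 2.30 and 1.74 with anti-CD40, and the JAK-STAT list 1.94 and 2.07 with IL-21.

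Stimulus effects changed between 2 h and 4 h for 2425 genes in GC B cells and 3666 in naive B cells (4966 and 6433 with the replicate block). The counts were 1519 and 2572 without the set term, and 2046 and 2492 with a set term for each time. Taken at each time alone, anti-CD40 called 957 genes at 2 h and 2502 at 4 h in GC B cells, and 1983 and 4743 in naive B cells. For IL-21 plus anti-CD40 the counts were 1019 and 3951 in GC and 1799 and 5167 in naive B cells. For anti-IgM they were 675 and 885 in GC and 2090 and 4116 in naive B cells.

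Other lists moved with the stimuli as well. Genes of light zone activation and positive selection rose with anti-CD40, 9 of 13 in GC B cells, with Slamf1 at 2.02 and Cd83 at 2.53, and 8 of 13 in naive B cells, with Il4i1 at 4.91 (adjusted p = 0.00014 and 0.011 with an estimated correlation). Of 10 cytokine and chemokine genes 6 rose with anti-CD40 in each cell type, including Lta (2.24 and 2.03) and Tnf (2.13 and 1.44), and Il10 reached 7.12 ± 0.78 in GC B cells with IL-21 plus anti-CD40. Of 14 genes of costimulation and antigen presentation 5 rose with anti-CD40 in GC B cells, with Cd69 at 3.32 and Icam1 at 3.01, while Ciita, the activator of MHC class II genes, fell (-1.23). The plasma cell list did not pass with any stimulus against no stimulation: with anti-IgM plus anti-CD40 in GC B cells Prdm1 and Irf4 rose while Mzb1 (-1.57) and Sec11c (-0.90) fell, and the median of the list (-0.05) and its test (up, adjusted p = 0.89) differed in sign. Heat shock genes rose in naive B cells with anti-IgM plus anti-CD40, 7 of 8, with Hspd1 at 1.17 (adjusted p = 0.034, and 0.061 with an estimated correlation). Genes of the p53 list went both ways, with Aen at 1.21 and Trp53inp1 at -1.33 with anti-CD40 in GC B cells. The NK cell gene Klrb1c was higher there by 2.35 ± 0.66.

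Library sets differed among libraries given the same stimulus, anti-CD40, the only one both contain. Whether the set difference depends on the stimulus could not be judged. The effects of IL-21 against no stimulation rest on the assumption that it does not. Between sets 3959 genes differed in GC and 4172 in naive B cells. The ribosomal RNA transcript Rn45s was higher in set A, by a fitted 4.35 in GC and 4.10 in naive B cells. It held the top value in 4 of 5 GC anti-CD40 libraries of that set and lay near the top in naive ones. A transcript at or near the top of a shared scale may have its difference understated. Lars2 was higher in set A by 5.27 in GC and 4.71 in naive B cells. Over all stimuli the myeloid marker Lyz2 ran from 4.023 to 5.42 in GC libraries of set A and from 0.576 to 2.765 in set B. In naive libraries its ranges overlapped, at 5.174 to 6.556 and 3.94 to 6.918. Among GC libraries of set B Rn45s was 10.04 and 11.42 without stimulus at 2 h, against 10.29 and 10.27 with anti-CD40, and 12.28 and 12.71 against 9.45 and 10.54 at 4 h. Xist, which is transcribed from the inactive X chromosome of females, differed in naive libraries by -9.56, set A minus set B, and the Y-linked Ddx3y was higher there by 11.8. In GC libraries Ddx3y was higher in set A by 8.20 while Xist was at -0.50 (adjusted p = 0.47). By these transcripts naive libraries of set A look male and those of set B female. Comparisons of IL-21 with no stimulation in naive B cells therefore coincide with a difference in sex. The set term removes it only so far as it is the same for every stimulus. Xist did not switch in this way in GC libraries, so differences between cell types in the effects of IL-21 share this limit.

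**Figure D3:**
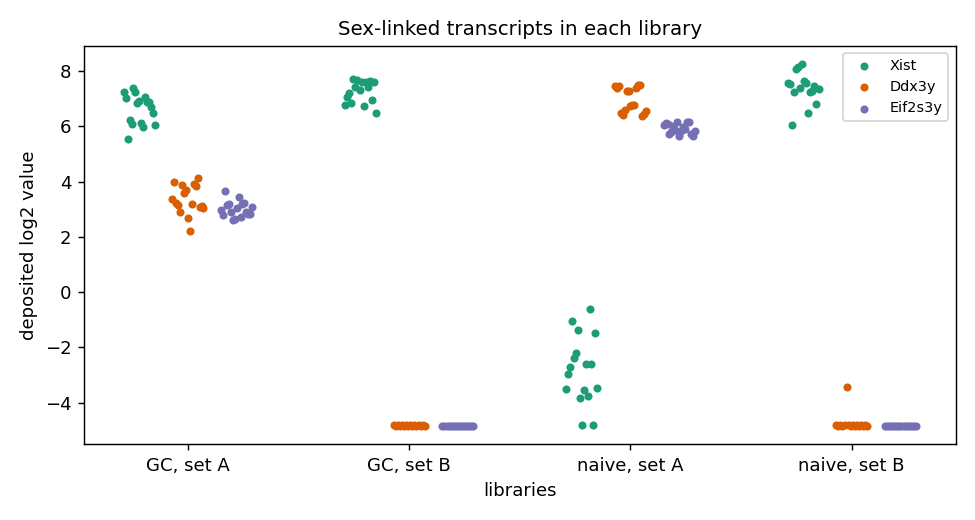
Deposited log2 values (vertical axis) of Xist, Ddx3y and Eif2s3y in every library, by cell type and library set (horizontal axis). Ddx3y averaged 3.36 in GC and 6.97 in naive libraries of set A, against -4.83 and -4.74 in set B.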

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

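Some libraries stood apart from the rest of their group in a focus gene, by the gap to the nearest library relative to the range of the group. Of 108 groups of values tested this way 12 stood out, and chance alone gives about 1 in 20. In naive B cells with anti-CD40 at 2 h, replicate 4 had Irf4 at 8.33 against 9.83 to 10.24 in the others, Bach2 at 5.59 against 6.67 to 6.83, Nr4a1 at 9.63 against 10.43 to 10.65 and Slc2a1 at 6.41 against 6.64 to 6.72. At 4 h replicate 4 had Bach2 at 5.62 and Cd83 at 12.91. In GC B cells with anti-CD40 at 4 h, Irf4 was 9.53 and Slc2a1 6.17 in replicate 4, Foxo1 5.70 in replicate 1 and Pim1 9.66 in replicate 2. At 2 h replicate 5 of the GC B cells had Prdm1 at -1.31 and Egr2 at 4.35. Prdm1 was near the filter's log2 value of 1 in the others of that group, at 0.8 to 1.24. Replicates 4 and 5 belong to library set B and replicates 1 to 3 to set A, so these groups mix sets that were normalized separately.

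Effects of a stimulus differed between GC and naive B cells, by the interaction test, for 1018 genes with anti-CD40, 1877 with anti-IgM, 2242 with anti-IgM plus anti-CD40, 69 with IL-21 and 658 with IL-21 plus anti-CD40. They differed between 2 h and 4 h for 2425 genes in GC and 3666 in naive B cells. Among focus genes, the GC effect minus the naive effect of anti-CD40 was 1.20 for Myc, -2.34 for Bcl6, 1.78 for Prdm1, -1.06 for Pim1, 2.02 for Batf, 1.23 for Nfkbia, 0.79 for Cd83, -1.15 for Ccnd2, 1.10 for Ccne1 and 0.76 for Cd40. For anti-IgM it was -1.19 for Myc, 1.78 for Prdm1, -1.41 for Socs1, -0.94 for Pim1, 1.17 for Egr1, -1.01 for Tnfaip3, -2.71 for Ccnd2, -1.64 for Bcl2l1 and 0.71 for Cd40.

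For anti-IgM plus anti-CD40 the difference was -1.09 for Bcl6, 3.49 for Prdm1, -1.36 for Socs1, -0.89 for Pim1, 1.61 for Batf, 1.06 for Egr1, 1.78 for Nfkbia, 1.08 for Cd83, -1.39 for Ccnd2, -0.84 for Bcl2l1 and 1.55 for Cd40. For IL-21 it was -2.84 for Bcl6 and -1.46 for Il21r. For IL-21 plus anti-CD40 it was 2.09 for Myc, -3.56 for Bcl6, 2.47 for Socs3, -2.07 for Socs1, -1.15 for Pim1, 1.34 for Egr2, 1.39 for Nfkbia, 1.23 for Ccne1, 0.87 for Slc2a1 and -0.87 for Il21r.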

How the results depend on the processing

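The replicate numbers of the file headers, a set term for each time, median scaling, other moderation and fits within a set were chosen after seeing the data. Of 904 named results, 786 kept their direction and side of the threshold whichever library was left out, 74 lost and 44 gained a call at least once, and none of those 904 reversed. The replicate block kept 798, with 2 weaker and 104 stronger. Leaving out the set term kept 822, with 19 weaker, 59 stronger and 4 reversed, all in GC B cells: with IL-21, Rn45s, which held the top value in all 6 GC libraries with IL-21, at 3.04, Bach2 at -0.98 and Slc2a1 at -0.34, and with IL-21 plus anti-CD40, Bach2 at -1.03. Fits within a library set kept 540 of 608, with 53 weaker and 15 stronger. No filter kept 878, the stricter filter 897 of 900, and separate fits 655 of 676. Relative to the median of all values, library medians lay at -0.09 in set A and 0.09 in set B. Median scaling removed this offset, which the set term absorbs, so it says nothing of robustness to scaling. The cause of these changes was not tested. Read depth is unknown, so its effect on low genes could not be assessed, and size factors from counts and tests on counts, with the lists under those size factors, were not run. Where an arm was left with 1 library, it was assumed to vary like the other groups.

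Without the set term the counts became 4360 for anti-CD40 (GC), 4929 and 4718 for IL-21 (GC and naive), 6780 and 6687 for IL-21 plus anti-CD40, 3269 and 3930 for anti-IgM plus anti-CD40 against anti-CD40, 3260 for IL-21 plus anti-CD40 against anti-CD40 (GC), 330 and 532 for departures with IL-21, 1652, 1358 and 3385 for cell type differences with anti-CD40, IL-21 and both, and 1519 for time (GC). A separate fit gave 38 departures with anti-IgM (GC).

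With the replicate block the counts were, and in brackets with the header numbers: anti-CD40 GC 3888 (3912), anti-IgM GC 2685 (2712), IL-21 920 (907) GC and 2397 (2436) naive, IL-21 plus anti-CD40 GC 4507 (4514), added anti-IgM 3069 (3066) and 3835 (3866), added IL-21 3512 (3547) and 2304 (2326), departures with anti-IgM 303 (295) and 2448 (2460), departures with IL-21 705 (717) and 1066 (1067), cell type differences for anti-CD40 2319 (2321), anti-IgM 3368 (3371), anti-IgM plus anti-CD40 3700 (3703), IL-21 312 (311) and IL-21 plus anti-CD40 1643 (1660), time 4966 (5022) and 6433 (6482). Of 600 list tests 211 passed, 221 with the block and 107 with an estimated correlation.

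Within a library set, with fewer libraries, the counts were 1571 for anti-CD40 and 1019 for anti-IgM (GC), 1049 for added anti-IgM (GC), 18 and 388 for departures with anti-IgM, 463, 997 and 1342 for cell type differences with anti-CD40, anti-IgM and both, and 3739 and 2738 for added IL-21. Leaving out 1 library, departures with anti-IgM (GC) ran from 33 to 74, departures with IL-21 (naive) from 216 to 447, and cell type differences with IL-21 from 40 to 78.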

Other observations

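Tests chosen after the result was seen were those of the mirrored replicates, of Xist, and of naive transcripts that no stimulus raised. Naive B cells given anti-IgM plus anti-CD40 fell short of the summed log2 effects in metabolic genes too: 8 of 17 genes of amino acid transport and the ATF4 response lay below the sum and 0 above (limma, adjusted p = 0.0031 with an estimated correlation). Of 11 quiescence genes 6 lay above it.

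A ceiling of the response could account for part of the shortfall in naive B cells. Among 395 genes raised by both single stimuli at 2 h, the median departure at 4 h was -0.62 (quartiles -1.07 and -0.18), 83.3% of them were negative, and 143 passed as negative against 3 as positive. A ceiling does not cover the 537 genes raised by anti-CD40 and not by anti-IgM, whose median was -0.31, with 72.1% negative and 92 passing as negative against 9 as positive. Nor does it cover genes that ended lower with both stimuli than with anti-CD40 alone, such as Ebi3 and Birc3 above. In naive libraries of set B Bcl2l1 averaged 7.85 with both stimuli against 9.04 with anti-CD40 at 4 h, and 7.47 against 7.57 at 2 h. That anti-CD40 opposes anti-IgM was left open: 580 genes raised by anti-IgM and not by anti-CD40 had a median of -0.12, with 57.8% negative and 83 passing as negative against 30 as positive. In GC B cells, 97 genes raised by both single stimuli at 2 h had a median departure of -0.21 at 4 h. Of these 64.9% were negative, and 2 passed as negative against 5 as positive. The 4 h unstimulated libraries enter every one of these departures. The choice of genes at 2 h was also not independent of the departure at 4 h. Through the set term, which both times share, anti-CD40 libraries of each time enter both anti-CD40 estimates, with errors that tend to go together. Anti-CD40 counts negatively in a departure, so choosing genes raised by it can itself push the median down. This holds for the 395, the 537 and the 97 genes, by an amount not tested.

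Replicates of set B mirrored each other between cell types. Across 11264 genes the difference between replicates 1 and 2 in GC libraries correlated at -0.93 with that in naive libraries, and its mean size of 0.46 in GC and 0.51 in naive libraries shrank to 0.10 when averaged over cell types. A replicate difference removed over both cell types together could give this. Mice or cultures shared by both cell types would give a positive correlation, but such a removal would take that shared part away. The correlation therefore cannot tell whether mice or cultures were shared. In set B the Y-linked Ddx3y, at the floor there, was -4.819 in replicates 1 and 4 of both cell types. It was -4.847 in replicates 2 and 5, except for -3.423 in naive unstimulated replicate 2 at 2 h. Such a removal would leave a step of this kind in a transcript that is absent. If a replicate difference was removed before deposit, the 40 residual degrees of freedom are too many and the p-values of all comparisons, which share this fit, may be too small, by an amount not tested. The main fit also leaves the pairing by replicate number in its residual. With the replicate block every comparison called more genes, from 1.14 to 5.05 times the main count. Which way the p-values err was thus not settled. In set A the correlations were 0.04, 0.09 and 0.07, by ranks 0.18, 0.31 and 0.30, and no biological explanation was tested. These weak correlations do not show that set A was left unadjusted, since values there also stepped by replicate number. In its naive libraries Cd74 was 14.671 in replicate 1, 14.647 in replicate 2 and 14.623 in replicate 3, whatever the stimulus or time.

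Y-linked transcripts appeared in GC libraries of set A, which also hold Xist, at 8.20 (Ddx3y), 13.3 (Eif2s3y), 8.23 (Kdm5d) and 14.9 (Uty) percent of the naive level of that set. Material from the naive preparations would bring their other transcripts at a like share. For 12 such transcripts the median was 5.89 percent, above the bound set beforehand for excluding this and below the share it needs. For the 7 of them that no stimulus of set A raised in GC B cells the median was 4.35 percent and 6 lay under the smallest Y-linked share, which argues against it as the whole source. GC B cells of male mice in the pool could not be told apart from other sources, since Xist, at -0.50 with a standard error of 0.51, decides nothing.

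For IL-21 plus anti-CD40 against anti-CD40 alone, the real grouping of set A libraries gave more genes than any other split drawn. The splits exchange libraries that may be technical replicates, so they cannot exclude chance differences between preparations. They also concern a fit within set A, not the counts of 2006 and 1208 given above. In a fit to the 11 GC libraries of set A 3149 genes passed, and 1 of 100 splits, the real one, gave as many, with 3011 as the highest other, a near mirror of the real split that exchanged all 6 labels at 4 h and kept 1 of 5 at 2 h. In the 12 naive libraries 2819 passed, again in 1 of 100 splits, with 1255 as the highest other.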
